A study of Mus musculus with 15 samples.

How the data were processed

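Total RNA of whole dorsal skin from male SKH-1 mice was sequenced in 15 libraries of 5 groups, 3 per group. Vehicle or agent was applied in 30 µL over 2 × 2 cm of skin, PAO at 25 µg/cm2 and CEES at 500 µg/cm2, and SNX-5422 followed 15 min later where given. Per the labels' protocols, RNA was extracted with an Aurum kit and depleted of ribosomal RNA with Ribo-Zero Gold. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.18.0.12, trimmed with Trim Galore 0.6.7, aligned to GRCm39 with STAR 2.7.10a and counted per gene with HTSeq 2.0.2. The deposited values are raw counts per gene, one table for all libraries. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands, and near-identical copies, are uncertain.

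Groups were taken from the sample titles and treatments. The titles of the SNX-5422+CEES libraries all carry number 1, and these libraries were numbered in the order of their records. The labels do not say that each library came from a separate animal, although doses are given per mouse. The p-values therefore measure the spread between these samples, which may be technical in part. Genes are given by the Ensembl identifiers of the table, and symbols were looked up by identifier, where 52093 of 53700 had a symbol and 1607 had none. The reference at hand was of another build (GRCm38), so it served for names only and no coordinates are given.

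The 5 summary entries of the table were kept out of library sizes and tests. Reads without a feature made up 35.2 to 46.9% of each library, ambiguous reads 2.08 to 2.53% and reads with more than a single alignment 4.78 to 9.76%. Mitochondrial ribosomal RNA took 5.72 to 17.7% of gene counts. Counts on genes ranged from 16838000 to 28887000 per library (rounded to 5 digits). Between replicates of a group the chi-square per degree of freedom of the counts was 6.99 to 50.2 among genes with at least 20 counts, so no pair looked like a duplicate.

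All comparisons came from 1 edgeR 4.0.16 quasi-likelihood fit of the 15 libraries (R 4.3.3) with a mean per group and 10 residual degrees of freedom. Libraries were scaled with TMM (factors 0.820 to 1.19). filterByExpr with its defaults left 22529 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values, named as the first group minus the second, with standard errors taken from the F statistic. Means and SDs are in CPM on TMM-scaled libraries. The comparisons were PAO and CEES with control, SNX-5422+PAO with PAO, SNX-5422+CEES with CEES, both SNX-5422 groups with control, CEES with PAO, the difference between the SNX-5422 effects, and their mean. The design, the 28 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined.

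Gene lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2) at its preset correlation of 0.01, with adjustment over the 28 lists. camera was repeated with a correlation estimated for each list, and fry was run beside it. camera compares a list with the other genes, and fry asks whether its members move on balance in a single direction without such a comparison. The lists covered the HSP90 and heat shock response, the unfolded protein and integrated stress response, NRF2 targets, metallothioneins, p53 targets, mitotic and S phase genes, cytokines and chemokines, neutrophil, monocyte and macrophage, T cell, Langerhans cell and mast cell, endothelial, adipocyte, nerve and melanocyte markers, interferon-stimulated genes, wound keratins and stress genes, the cornified layer, basal keratinocytes, hair follicle keratins, fibroblast and matrix genes, matrix proteases, sebaceous and cholesterol synthesis, skeletal muscle, blood, mitochondrially encoded genes, glucocorticoid receptor targets, immediate early and AP-1 genes, hypoxia and glycolysis, and cell death.

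Genes were named by rule. In the 4 main comparisons these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in a group, no overlap in CPM between the groups compared and an ordinary symbol. In the other comparisons 3 of each were named. From each list up to 2 raised and 2 lowered members with the smallest p could be named, and Hsp90aa1, Hsp90ab1, Hsp90b1 and Trap1 always were. Genes with 3 counts or fewer over a group have a ratio with a 95% interval for counting error only. Genes at 0 have a bound set at 3 counts over the group. Counts of reads are not counts of independent molecules.

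Overlaps between comparisons that share libraries were set beside 20 simulated data sets, with all groups equal or with the agent effect alone. The simulations drew genes independently from negative binomial distributions, so they leave out variation that genes share. Scores of the other agent's genes were compared with exact permutation tests. On counts simulated for SNX-5422+PAO against PAO, with 200 of 21659 genes changed, the test recovered 23.9% of genes changed by 1.5-fold, 64.2% at 2-fold and 95.5% at 4-fold. Of 132 calls, 5 were of unchanged genes. For this comparison camera called 0 of the real lists in the simulated counts and fry 1, and both called a simulated list of 20 genes changed by 1.5-fold.

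Alternatives were DESeq2 size factors, upper-quartile and total-count scaling, no filter, a filter of more than 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, a fold change above 2, a fit of the groups compared alone, the mean of the muscle list as a covariate, a fit without muscle, fat, blood and mitochondrial genes, a replicate block, and each library left out in turn. After the data were seen, a list of 40 pancreatic genes (20 islet, 20 acinar, 38 of them tested) was drawn up. Fits without these genes, with their mean as a covariate, without ribosomal RNA and the most abundant unnamed identifiers, and with the mean of both mitochondrial ribosomal RNAs as a covariate were added then. The closing section gives their effect.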

Results

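RNA-seq counts of whole dorsal skin from male SKH-1 hairless mice were compared in 15 libraries, 3 in each of 5 groups, 24 h after topical treatment. Control skin received the vehicle. Phenylarsine oxide (PAO), a trivalent arsenical that binds neighbouring thiols, was given at 100 µg per mouse. 2-Chloroethyl ethyl sulfide (CEES), a monofunctional analog of sulfur mustard that alkylates DNA and protein, was given at 2 mg per mouse. In a further group for each agent, SNX-5422, an inhibitor of the chaperone HSP90, was applied at 20 mg/kg 15 min after the agent. No group used here received SNX-5422 without an agent. The median count on genes per library was 20512000, and 22529 genes were tested. The first principal component held 35.9% of the variance. CEES libraries lay between 64.5 and 78.3 on it, SNX-5422+CEES libraries between 29.7 and 49.3, and control libraries between -54.1 and -40.1.

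The libraries differed in transcripts of muscle, which lies beneath the dermis, and in those of the pancreas, which is no part of skin. The skeletal muscle list took 8.96% ± 2.45 (SD, n = 3) of gene counts in control, 9.07% ± 0.302 in PAO, 11.2% ± 0.965 in SNX-5422+PAO, 4.06% ± 0.333 in CEES and 7.87% ± 0.998 in SNX-5422+CEES libraries. Transcripts of the pancreas, gathered in a list of islet and acinar genes drawn up after the data were seen, took 0.224% ± 0.169, 0.168% ± 0.0352, 0.219% ± 0.0420, 0.00348% ± 0.000321 and 0.0131% ± 0.00939 in the same order. Mitochondrial ribosomal RNA took 7.44% ± 0.80, 13.4% ± 4.01, 15.6% ± 2.88, 7.43% ± 1.87 and 8.58% ± 0.454. In a check chosen after the data were seen, its share within the PAO and SNX-5422+PAO groups, centred on each group, ran against the mean log2 CPM of the cytokine list (Pearson r = -0.98 over 6 libraries, permutation p = 0.0281), the heat shock list (-0.96, 0.0281), neutrophil markers (-0.94, 0.0281), monocyte markers (-0.82, 0.0842) and the cornified layer (-0.50, 0.251). Permuting within groups of 3 libraries allows few arrangements, so 0.0281 is about the smallest p possible over these 6. Over all 15 libraries r was -0.46 for cytokines (permutation p = 0.204), -0.80 for heat shock genes (0.0353), -0.26 for neutrophil (0.378) and -0.42 for monocyte markers (0.245) and -0.49 for the cornified layer (0.0386).

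**Figure D1:**
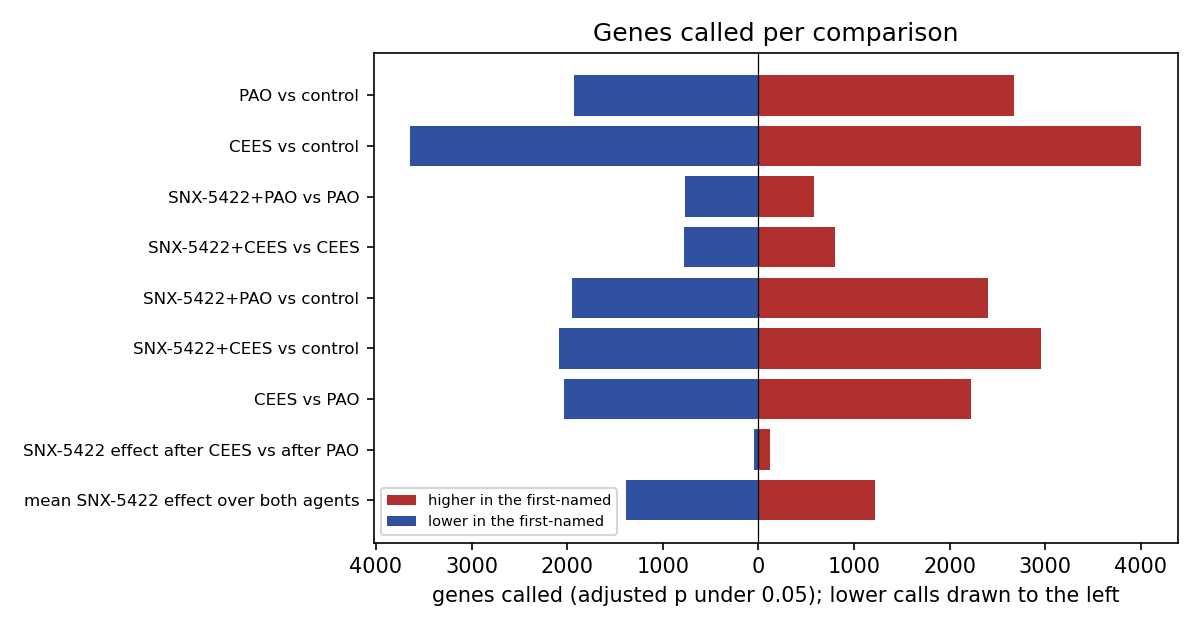
Numbers of genes called by edgeR (adjusted p under 0.05) in each comparison, raised and lowered genes drawn apart. CEES against control gave the most calls (4000 raised, 3640 lowered) and the difference between the SNX-5422 effects the fewest (124 raised, 42 lowered).

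The first comparison asked what skin expressed differently 24 h after PAO. camera at its preset correlation called 20 of 28 lists, among them heat shock genes, NRF2 targets, cytokines, myeloid markers and interferon-stimulated genes as raised and the cornified layer and sebaceous lists as lowered. With an estimated correlation it called 1 list, the glucocorticoid receptor targets (adjusted p = 0.0474), and the lists just named had an adjusted p of 0.16 to 0.23 with an estimated correlation. edgeR called 4607 genes, 2673 raised and 1934 lowered, of which 859 and 743 changed by more than 2-fold. Without PAO 1 or PAO 3 it called 2953 and 2998, and with mitochondrial ribosomal RNA as a covariate 2035, of which 1839 were among the 4607. That covariate ended the calls of Krtap4-6 (log2 fold change -1.94, adjusted p = 0.327), Krtap3-1 (-2.27, 0.225), Cd207 (-1.71, 0.0834) and Trap1 (0.16, 0.432). Upper-quartile scaling turned the split to 2183 raised and 2497 lowered. Total counts gave 1434 and 4342, with the median of all genes shifted by -0.20 on the log2 scale.

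Among the 6 largest rises after PAO, Retnlg, a neutrophil product, rose by 5.88 ± 0.93 (log2 fold change ± SE, adjusted p = 0.000347). The acute-phase gene Saa3 rose by 5.86 ± 0.43, from 3.04 ± 0.314 to 178 ± 97.9 CPM (SD, n = 3, adjusted p = 4.01e-07). Ankrd1, a gene of muscle stress, rose by 5.24 ± 0.28, from 8.08 ± 4.17 to 303 ± 66.3 CPM. Fgf23 rose by 5.49, Chil3 by 5.32 and Slfn4 by 5.08. The suprabasal keratin Krt2 changed by -4.35 ± 0.69 (adjusted p = 0.000336). The muscle kinase Mylk4 changed by -3.89 ± 0.38, from 255 ± 96.2 to 17.2 ± 0.838 CPM, and its neighbours in size were Aqp4 (-3.13) and Tmem233 (-3.06). The hair keratin-associated genes Krtap4-6 and Krtap3-1 changed by -2.98 and -2.88, and belong to a family of near-identical genes whose counts are uncertain.

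Of the 20 genes of the HSP90 and heat shock list, 14 rose after PAO and none of the others was called, or 15 adjusted over the list alone, with a median of 0.66 (adjusted p = 0.175 with an estimated correlation). The small heat shock protein Cryab rose by 2.79 ± 0.19, from 101 ± 2.46 to 698 ± 209 CPM, and the co-chaperone Bag3 by 1.36 ± 0.13. Among the HSP90 genes themselves, Hsp90aa1 rose by 1.18 ± 0.18 (adjusted p = 0.000218), Hsp90ab1 by 0.43 ± 0.09 (adjusted p = 0.00379) and Hsp90b1 by 0.49 ± 0.11 (0.32 without PAO 1). Trap1, the mitochondrial member, rose by 0.22 ± 0.08 (adjusted p = 0.0492). That call ended without any 1 library other than SNX-5422+CEES 1, at adjusted p from 0.05 to 0.223. The unfolded protein and integrated stress list had 14 of 20 raised (15 adjusted over the list alone, median 0.48, adjusted p = 0.195 with an estimated correlation), such as Trib3 (1.90) and Dnajb9 (0.85). NRF2 targets had 10 of 17 raised and 1 lowered (12 and 1 adjusted over the list alone, median 0.80, adjusted p = 0.175 with an estimated correlation), led by Srxn1 (2.38 ± 0.20) and Sqstm1 (1.49 ± 0.13).

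Inflammatory cytokines and chemokines had 15 of 23 raised and 2 lowered after PAO (16 and 2 adjusted over the list alone, median 1.49, adjusted p = 0.23 with an estimated correlation). Cxcl5 rose by 4.47 ± 0.49 and Cxcl1 by 3.04 ± 0.33, while Il1a changed by -1.65 ± 0.28. Neutrophil markers had 11 of 16 raised and 1 lowered (14 and 1 adjusted over the list alone, median 1.99, adjusted p = 0.23 with an estimated correlation), with Mmp8 at 3.45. Monocyte and macrophage markers had 13 of 15 raised (14 adjusted over the list alone, median 1.54), interferon-stimulated genes 15 of 18 (17, median 1.13), and matrix proteases 13 of 18 raised and 1 lowered (14 and 1, median 1.01). The adjusted p was 0.175 with an estimated correlation for each of these 3 lists. Lyz2 rose by 1.56, Oasl1 by 3.37 and Mmp3 by 4.29 ± 0.36 (6.46 ± 0.966 to 127 ± 56.5 CPM). Cd207, a Langerhans cell gene, changed by -2.40 and Cd3e by -1.43, within a T cell, Langerhans cell and mast cell list of 4 lowered among 14 (4 adjusted over the list alone, median -0.35) that camera did not call.

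All 20 genes of the cornified layer list fell after PAO, also adjusted over the list alone, with a median of -1.80 (adjusted p = 0.16 with an estimated correlation). Krt10, the main keratin of differentiating epidermis, went from 1336 ± 379 to 303 ± 25.7 CPM (-2.14 ± 0.26) and Krt77 changed by -2.40. Sebaceous and cholesterol synthesis genes had 16 of 18 lowered (17 adjusted over the list alone, median -0.75, adjusted p = 0.175 with an estimated correlation), with Lss at -0.81 and Dhcr7 at -0.69. Wound keratins and stress genes went both ways, 4 raised and 4 lowered among 15 (4 and 5 adjusted over the list alone), with Krt6b at 2.86 ± 0.28 and Lcn2 at 3.83 but Sprr1a at -1.48. Glucocorticoid receptor targets had 8 of 13 raised and 1 lowered (9 and 1 adjusted over the list alone, median 0.47). They were the 1 list of 28 called with an estimated correlation (adjusted p = 0.0474), and fry called 18. Cebpd in it rose by 1.08 ± 0.14.

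Other lists that camera called after PAO were those of fibroblast and matrix genes (9 of 17 raised, 12 adjusted over the list alone, median 0.63, adjusted p = 0.444 with an estimated correlation), with Pdgfra at 2.00, and of hypoxia and glycolysis genes (8 of 15 raised, 9 over the list alone, median 0.53, adjusted p = 0.444 with an estimated correlation). Basal keratinocyte genes (7 of 14 raised and 1 lowered, 7 and 2 over the list alone, median 0.28) had 0.444 with an estimated correlation too. Cell death genes had 7 of 17 raised and 2 lowered (9 and 3 over the list alone, median 0.24, adjusted p = 0.269 with an estimated correlation), with Nlrp3 at 1.96 and Gsdma at -1.08. Endothelial markers had 3 of 12 raised (7 over the list alone, median 0.74, adjusted p = 0.54 with an estimated correlation). Adipocyte markers had 2 raised and 6 lowered of 13 (2 and 9 over the list alone, median -0.71, adjusted p = 0.456 with an estimated correlation). Hair follicle keratins had a median of -1.34 with 1 of 20 lowered (adjusted p = 0.506 with an estimated correlation). p53 targets had 5 of 20 raised and 1 lowered (the same numbers over the list alone), with Eda2r at 1.76, and a median of 0.13 that turned to -0.07 under total counts (adjusted p = 0.429 with an estimated correlation). Nerve and melanocyte markers had a median of -0.54 (adjusted p = 0.297 with an estimated correlation).

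Lists that camera did not call after PAO held single genes that changed. Metallothioneins had 3 raised and 2 lowered of 7 (the same over the list alone), and Mt1 rose by 2.62 ± 0.21, from 54.0 ± 12.3 to 330.1 ± 21.3 CPM. Immediate early and AP-1 genes had 7 raised and 3 lowered of 16 (the same over the list alone), with Fos at 1.15 and Egr3 at -0.85, and a median of 0.10 that became -0.11 under total counts. Mitotic and S phase genes had a median of -0.13 with 3 of 20 lowered (2 over the list alone). Skeletal muscle genes had 1 raised and 1 lowered of 17, with Des at 0.79 ± 0.14. Their median of 0.03 turned to -0.04 under upper-quartile scaling and to -0.16 under total counts. Mitochondrially encoded genes and blood genes had medians of 0.09 (-0.10 under total counts) and -0.06.

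The next comparison asked the same of CEES. camera at its preset correlation called 20 of 28 lists, among them cytokines, myeloid, fibroblast and endothelial markers, matrix proteases, p53 targets and cell death genes as raised and muscle and mitochondrially encoded genes as lowered. With an estimated correlation it called 0 lists, with 8 at an unadjusted p under 0.05, a lowest adjusted p of 0.128, and 19 called by fry. edgeR called 7640 genes, 4000 raised and 3640 lowered, of which 1808 and 1278 changed by more than 2-fold. The 2 groups given CEES carry library codes 13 to 18 and the other groups 1 to 9. Separate handling therefore cannot be told apart from treatment wherever a group given CEES is compared with control or PAO. Upper-quartile scaling turned the split to 3507 raised and 4556 lowered, and total counts gave 5049 and 2409, with the median of all genes shifted by 0.12.

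Among the 6 largest rises after CEES, Lce3d had 0 counts in the control libraries and was at least 129-fold higher after CEES, taking 3 counts over the group as the floor, although Lce genes are near-identical copies. Il19 was higher by a ratio of 291 (95% counting interval 80.2 to 2409, covering counting error only). Il6 rose by 7.14 ± 0.69, from 0.158 ± 0.143 to 24.4 ± 2.08 CPM (SD, n = 3, adjusted p = 1.55e-06). Fgf23 rose by 7.36, Chil3 by 6.51 and Saa3 by 6.29 ± 0.43. The 6 largest falls were all in genes of the pancreas or of other secretory tissue. Ins2 averaged 699.7 ± 452 CPM in control, 660.0 ± 153 in PAO, 939.5 ± 210 in SNX-5422+PAO, 4.23 ± 1.26 in CEES and 33.8 ± 27.9 in SNX-5422+CEES libraries (-7.37 ± 0.64, adjusted p = 5.78e-07). Ins1 changed by -7.43 and Gcg by -7.84. The control to CEES ratio was 249 for Zg16 (interval 68.6 to 2063), 203 for Ppy (69.2 to 988) and 184 for Pcsk1n (50.5 to 1523). Muscle genes fell in the same libraries, 15 of 17 (16 adjusted over the list alone, median -1.11, adjusted p = 0.329 with an estimated correlation), Ttn by -1.40 ± 0.18, and so did 7 of 10 mitochondrially encoded genes (7 over the list alone, median -0.89, adjusted p = 0.329 with an estimated correlation).

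Cytokines and chemokines had 19 of 23 raised after CEES (20 adjusted over the list alone, median 3.80, adjusted p = 0.128 with an estimated correlation). Il1b rose by 4.37 ± 0.33, from 4.47 ± 0.538 to 92.4 ± 19.3 CPM, and Cxcl1 by 4.54 ± 0.33. Neutrophil markers had 15 of 16 raised (15 over the list alone, median 3.06, adjusted p = 0.159 with an estimated correlation), with Csf3r at 4.34. Monocyte and macrophage markers had 14 of 15 raised (15 over the list alone, median 1.83, adjusted p = 0.128 with an estimated correlation). The macrophage mannose receptor Mrc1 went from 35.3 ± 1.98 to 799 ± 233 CPM (4.50 ± 0.25). Fibroblast and matrix genes had 15 of 17 raised (17 over the list alone, median 1.80), matrix proteases 16 of 18 (16 raised and 1 lowered over the list alone, median 1.73), and cell death genes 13 of 17 raised and 1 lowered (13 and 1 over the list alone, median 0.82). Each of these 3 had an adjusted p of 0.128 with an estimated correlation. Lum rose by 2.76 ± 0.20, Pdgfra by 3.54, Timp1 by 3.22 and Nlrp3 by 3.47. Endothelial markers had 11 of 12 raised (11 over the list alone, median 1.56, adjusted p = 0.329 with an estimated correlation).

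p53 targets had 12 of 20 raised after CEES (13 raised and 2 lowered adjusted over the list alone, median 0.57, adjusted p = 0.128 with an estimated correlation). The death receptor gene Tnfrsf10b rose by 1.11 ± 0.12 (adjusted p = 3.13e-06) and Eda2r by 1.53. Mitotic and S phase genes had 11 of 20 raised (12 over the list alone, median 0.40, adjusted p = 0.469 with an estimated correlation), with Rrm2 at 0.89 and Mcm4 at 0.43. The unfolded protein list had 16 of 20 raised and 1 lowered (16 and 1 over the list alone, median 0.69, adjusted p = 0.212 with an estimated correlation), with the disulfide isomerases Pdia6 and Pdia4 both at 0.93. Heat shock genes had 7 of 20 raised and 1 lowered (7 and 1 over the list alone, median 0.25, adjusted p = 0.56 with an estimated correlation), among them Cryab (2.13) and Hspb1 (1.01). Hsp90aa1 rose by 0.91 ± 0.18 (adjusted p = 0.000785) and Hsp90b1 by 0.75 ± 0.11 (adjusted p = 6.71e-05). Hsp90ab1 stood at -0.075 (adjusted p = 0.573, 0.044 under total counts) and Trap1 at 0.13 (adjusted p = 0.197). NRF2 targets had 10 of 17 raised and 2 lowered (11 and 2 over the list alone, median 0.40, adjusted p = 0.56 with an estimated correlation), with Hmox1 at 1.78 and Gstm1 at -0.80.

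In the epidermis after CEES, wound keratins and stress genes had 7 of 15 raised and 1 lowered (7 and 1 adjusted over the list alone, median 1.05, adjusted p = 0.408 with an estimated correlation). Krt6b rose by 3.85 ± 0.29, from 25.6 ± 1.24 to 368 ± 43.9 CPM. Cornified layer genes had 9 of 20 lowered (11 over the list alone, median -0.73, adjusted p = 0.469 with an estimated correlation), with Ivl and Tgm3 both at -1.09. Basal keratinocyte genes had 3 raised and 7 lowered of 14 (the same over the list alone, median -0.23) and were not called by camera, although Col17a1 changed by -0.91 ± 0.10 and Trp63 by -0.51. Hair follicle keratins had 4 of 20 lowered (2 over the list alone, median -1.47, adjusted p = 0.56 with an estimated correlation). Glucocorticoid receptor targets had 8 raised and 2 lowered of 13 (8 and 2 over the list alone, median 0.53, adjusted p = 0.128 with an estimated correlation), with Cebpd at 1.99 and Pdk4 at -1.38. AP-1 genes had 10 raised and 3 lowered of 16 (the same over the list alone, median 0.53, adjusted p = 0.329 with an estimated correlation), and hypoxia genes 7 raised and 1 lowered of 15 (the same over the list alone, median 0.43, adjusted p = 0.56 with an estimated correlation), such as Fos (1.37) and Adm (3.28). The uncalled interferon-stimulated list had 3 raised and 3 lowered of 18 (5 and 3 over the list alone, median 0.34), with Cxcl9 at -2.51, and the uncalled sebaceous list had 2 raised and 4 lowered of 18 (the same over the list alone, median -0.16).

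Set directly against PAO, the cytokine, fibroblast and cornified layer lists were called higher after CEES and the heat shock, NRF2 and interferon lists lower by camera at its preset correlation. With an estimated correlation camera called 0 of 28 lists, with 5 at an unadjusted p under 0.05, a lowest adjusted p of 0.181, and 19 called by fry. edgeR called 4255 genes, 2222 higher and 2033 lower after CEES, and 2825 without PAO 3. The muscle covariate left 1688 genes and the mitochondrial ribosomal RNA covariate 827. Total counts gave 7067 and 796, with the median of all genes shifted by 0.32. Interferon-stimulated genes had 12 of 18 lower (14 adjusted over the list alone, median -1.21, adjusted p = 0.194 with an estimated correlation). Heat shock genes had 11 of 20 lower (14 over the list alone, median -0.37, or -0.055 under total counts, adjusted p = 0.204 with an estimated correlation), and NRF2 targets 9 of 17 lower and 1 higher (9 and 1 over the list alone, median -0.57, or -0.26 under total counts, adjusted p = 0.279 with an estimated correlation). Hsp90ab1 was lower by -0.50 ± 0.09 (adjusted p = 0.00131, and 0.144 with the muscle covariate), while Hsp90aa1 stood at -0.27 (adjusted p = 0.312), Hsp90b1 at 0.26 (adjusted p = 0.107) and Trap1 at -0.089 (adjusted p = 0.459). Under total counts Hsp90aa1 turned to 0.032 and Trap1 to 0.23 (adjusted p = 0.0369). Cornified layer genes had 13 of 20 higher (16 over the list alone, median 1.08, adjusted p = 0.194 with an estimated correlation), fibroblast genes 17 of 17 (17 over the list alone, median 1.25, adjusted p = 0.181 with an estimated correlation) and cytokines 18 of 23 (20 over the list alone, median 1.63, adjusted p = 0.181 with an estimated correlation). Adipocyte markers had 8 higher and 3 lower of 13 (9 and 4 over the list alone, median 1.48, adjusted p = 0.367 with an estimated correlation). Muscle genes had 14 of 17 lower (16 over the list alone, median -1.21) and mitochondrially encoded genes 7 of 10 (7 over the list alone, median -0.95), each at an adjusted p of 0.194 with an estimated correlation. The largest differences were Lce3c (5.18 ± 0.43), Iqcn (4.14 ± 0.44), Lce3d (ratio 145, interval 39.9 to 1203) and, lower after CEES, Gcg (-7.79), Ins1 (-7.36) and Ppy (ratio 200.27, interval 68.1 to 975).

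Both agents moved 3062 genes in the same direction, 1837 up and 1225 down, and 101 in opposite directions. Without PAO 1 the number was 1985, and with the mitochondrial ribosomal RNA covariate 1540. Lists drawn independently would share 475 and 312. Across genes, which are not independent replicates, the fold changes correlated at r = 0.62 with a covariance of 0.442. Simulated groups without any effect, set against shared controls, gave r = 0.489, a covariance of 0.0495 and at most 0 shared calls in 20 runs. They had 0.15 genes called for CEES per run, so the number of shared calls says nothing of what sharing controls adds. When each control entered only 1 of the comparisons, a check chosen after the data were seen that leaves 1 control alone in a comparison, the covariance over 6 divisions was 0.339 to 0.432 and r 0.383 to 0.567. No division keeps 2 controls on both sides, so part of the excess in calls may come from sharing them.

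**Figure D2:**
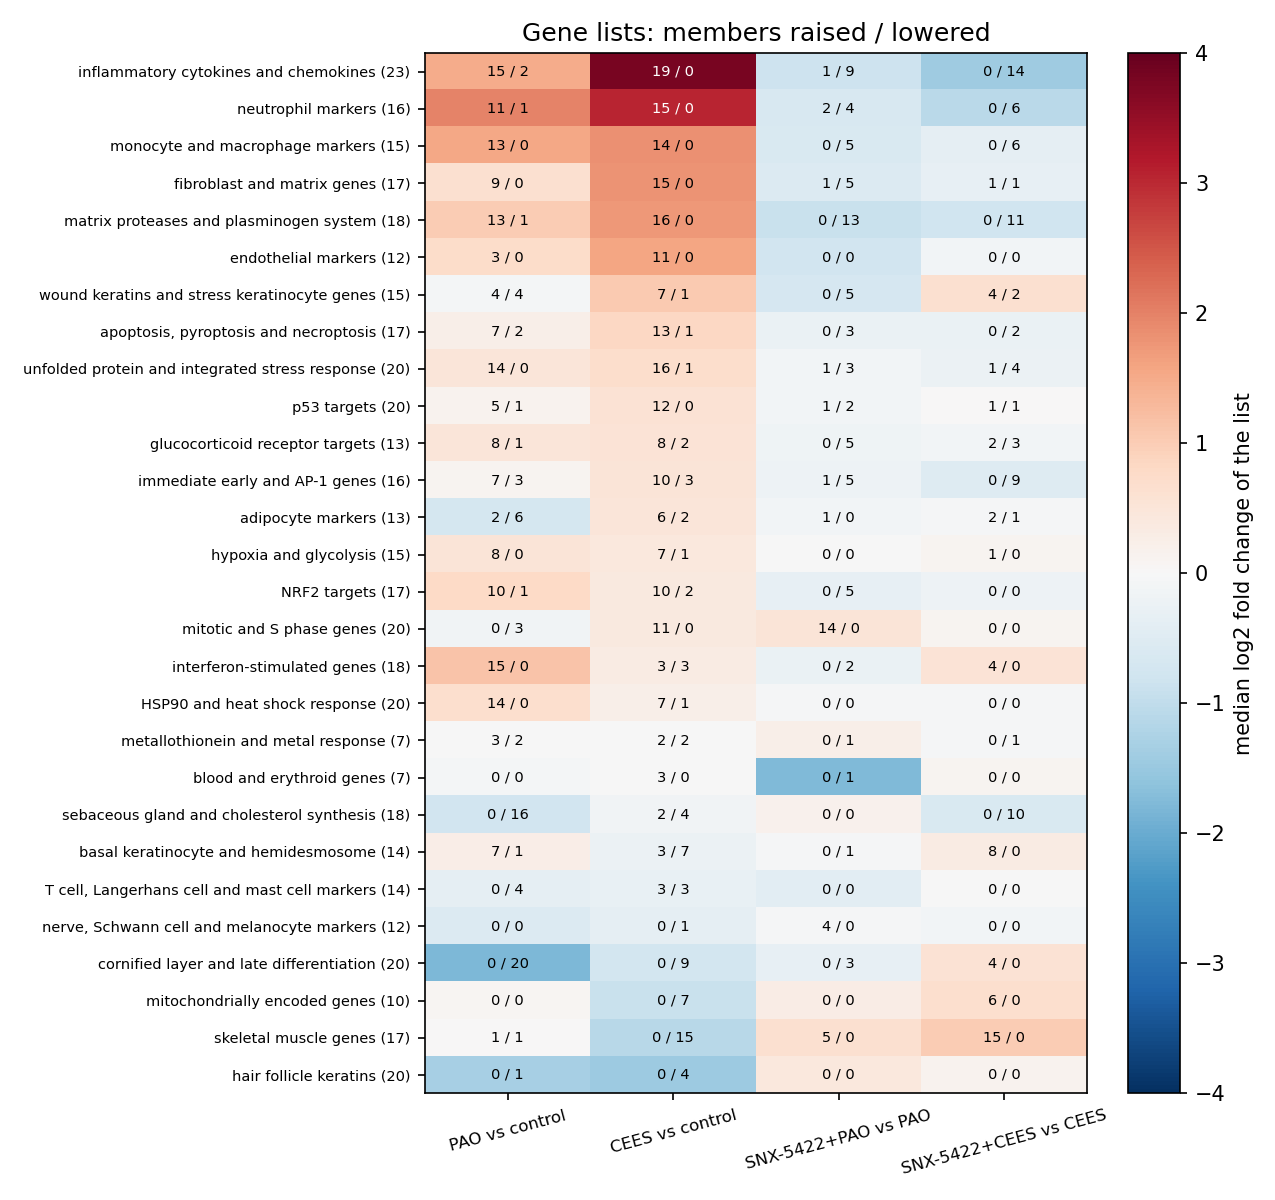
Median log2 fold change of each of the 28 gene lists (lines of the grid) for PAO and CEES against control and for SNX-5422 after each against that agent alone (columns), from blue (lower) to red (higher), with the numbers of members called raised and lowered written in. The cytokine list stood at 1.49 after PAO and 3.80 after CEES, and at -0.84 and -1.41 where SNX-5422 followed.

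SNX-5422 after PAO was compared with PAO alone, to ask what the HSP90 inhibitor changed in injured skin. camera at its preset correlation called 18 of 28 lists, most of them with a minority of members past the threshold. Matrix proteases (13 of 18 lowered) and mitotic genes (14 of 20 raised) had a majority. With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05, a lowest adjusted p of 0.105 (0.218 for both of these lists), and 7 called by fry. edgeR called 1343 genes, 579 raised and 764 lowered, of which 172 and 268 by more than 2-fold. The number was 661 without PAO 1, 600 without PAO 3, 566 without SNX-5422+PAO 2 and 586 without SNX-5422+PAO 3. Total counts gave 335 raised and 1568 lowered, with the median of all genes shifted by -0.13, a covariate for muscle content left 627 genes, and the mitochondrial ribosomal RNA covariate 933.

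The 6 largest rises with SNX-5422 after PAO were all in muscle genes, most of them of slow fibres. Myh7 was higher by a ratio of 1165 (95% counting interval 322 to 9625), from 0.0371 ± 0.0642 to 42.8 ± 36.0 CPM, and read 82.2, 11.8 and 34.3 CPM in the 3 SNX-5422+PAO libraries. Igfn1 rose by 8.27 ± 1.32, Myl2 by 4.75 ± 0.69, Tnnc1 by 3.95 ± 0.57 and Tnni1 by 3.75 ± 0.49. Mylk4, which PAO had lowered, rose by 3.39 ± 0.37 to 181 ± 61.0 CPM. With the muscle covariate Myh7 (adjusted p = 0.0606), Igfn1 (log2 fold change 5.88, adjusted p = 0.339), Myl2 (3.80, 0.0672) and Tnnc1 (3.40, 0.0711) lost their calls, as did Retnlg (-2.30, 0.362), Clec4e (0.82, 0.142), Fcgr1 (-1.19, 0.0813) and Pdgfra (-1.40, 0.0778). Skeletal muscle genes had 5 of 17 raised (12 adjusted over the list alone, median 0.64, adjusted p = 0.297 with an estimated correlation), with Tcap at 1.06 ± 0.17. Mitochondrially encoded genes had a median of 0.31 (adjusted p = 0.478 with an estimated correlation).

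Of the 6 largest falls with SNX-5422 after PAO, Klhdc8a changed by -2.70 ± 0.30, Mmp13 by -2.57 ± 0.34, Mmp3 by -2.52 ± 0.33 (127 ± 56.5 to 22.2 ± 7.44 CPM), Fgf23 by -2.81 and Slfn4 by -2.62. Retnlg changed by -3.12 ± 0.73 (adjusted p = 0.0183), a call that ended without PAO 1 (-2.73, adjusted p = 0.0762), SNX-5422+PAO 2 (-2.90, 0.0877) or SNX-5422+PAO 3 (-3.36, 0.0619). Matrix proteases had 13 of 18 lowered (1 raised and 13 lowered adjusted over the list alone, median -0.89, adjusted p = 0.218 with an estimated correlation). Cytokines had 9 of 23 lowered and 1 raised (12 and 2 over the list alone, median -0.84, adjusted p = 0.397 with an estimated correlation), led by the granulocyte factor Csf3 (-4.63 ± 0.60) and Cxcl1 (-2.05 ± 0.31). Monocyte markers had 5 of 15 lowered (9 over the list alone, median -0.61, adjusted p = 0.397 with an estimated correlation), such as Fcgr1 (-1.21). Neutrophil markers went both ways, 4 lowered and 2 raised of 16 (5 and 2 over the list alone, median -0.63, adjusted p = 0.639 with an estimated correlation), with Clec4e at 1.28. Wound keratins and stress genes had 5 of 15 lowered (6 over the list alone, median -0.68, adjusted p = 0.29 with an estimated correlation). Lcn2 changed by -1.93 ± 0.28 and Krt6b by -1.22 ± 0.26 (without PAO 1 -1.06, adjusted p = 0.0541).

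NRF2 targets had 5 of 17 lowered with SNX-5422 after PAO (6 adjusted over the list alone, median -0.34, adjusted p = 0.397 with an estimated correlation). Hmox1, the inducible heme oxygenase, went from 196 ± 89.2 to 38.2 ± 9.09 CPM (-2.36 ± 0.27) and Txnrd1 changed by -0.68 ± 0.12. Mitotic and S phase genes had 14 of 20 raised (19 over the list alone, median 0.52, adjusted p = 0.218 with an estimated correlation), with Mki67 at 0.73 ± 0.11 and Bub1 at 0.83 ± 0.13. Glucocorticoid receptor targets had 5 of 13 lowered (5 over the list alone, median -0.18, adjusted p = 0.105 with an estimated correlation), with Cebpd at -0.98. AP-1 genes had 5 of 16 lowered and 1 raised (6 and 1 over the list alone, median -0.19) and cell death genes 3 of 17 lowered (3 over the list alone, median -0.26), each at an adjusted p of 0.218 with an estimated correlation. Fibroblast genes had 5 of 17 lowered and 1 raised (10 and 2 over the list alone, median -0.55, adjusted p = 0.478 with an estimated correlation), with Pdgfra at -1.53 ± 0.29. Endothelial markers had a median of -0.76 (adjusted p = 0.478 with an estimated correlation), with 0 of 12 called by edgeR, 10 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom and 6 lowered over the list alone. Blood and erythroid genes, not called by camera, had the lowest median of all lists, -1.77, with 1 of 7 lowered (Hbb-bs, -2.37; 2 over the list alone) and 5 at an unadjusted p under 0.05. The call of Hbb-bs ended with the mitochondrial ribosomal RNA covariate (-2.01, adjusted p = 0.117). The melanocyte genes Pmel and Dct rose by 2.29 and 1.91. Cornified layer genes, all lowered by PAO, had 3 of 20 lowered further (4 over the list alone, median -0.32, adjusted p = 0.478 with an estimated correlation).

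The HSP90 and heat shock list itself had 0 of 20 genes called by edgeR when SNX-5422 followed PAO, with 3 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. Its median was -0.05. Hsp90aa1 stood at -0.24 ± 0.17 (adjusted p = 0.494) and Trap1 at 0.13 ± 0.08 (adjusted p = 0.359). Hsp90ab1 stood at -0.069 (adjusted p = 0.75, 0.008 without PAO 1) and Hsp90b1 at -0.059 (adjusted p = 0.824, 0.085 without PAO 1 and 0.013 without SNX-5422+PAO 2). When SNX-5422 followed CEES the same list had 0 of 20 called by edgeR, with 1 at an unadjusted p under 0.05 and 1 called by each of DESeq2 and limma-voom, and a median of -0.05. There Hsp90aa1 stood at -0.28 ± 0.17 (adjusted p = 0.417), Hsp90ab1 at 0.15 ± 0.09 (adjusted p = 0.413), Hsp90b1 at -0.24 ± 0.11 (adjusted p = 0.22) and Trap1 at 0.054 ± 0.08 (adjusted p = 0.775, -0.058 under total counts).

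SNX-5422 after CEES was compared with CEES alone for the same question. camera at its preset correlation called 15 of 28 lists. Among those with a majority of members past the threshold, cytokines (14 of 23), AP-1 genes (9 of 16), matrix proteases (11 of 18) and sebaceous genes (10 of 18) were lowered and basal keratinocyte (8 of 14), muscle (15 of 17) and mitochondrially encoded genes (6 of 10) raised. With an estimated correlation AP-1 genes were the 1 list called (adjusted p = 0.0329), and the other 6 had an adjusted p of 0.153 to 0.189. edgeR called 1576 genes, 797 raised and 779 lowered, of which 269 and 239 by more than 2-fold. It called 1002 without CEES 2, 928 without CEES 3, 878 without SNX-5422+CEES 2 and 806 without SNX-5422+CEES 3. Total counts gave 521 raised and 1266 lowered, with a shift of -0.11, and the muscle covariate left 727 genes.

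Of the 6 largest falls with SNX-5422 after CEES, 4 were in cytokine and chemokine genes. Il6 went from 24.4 ± 2.08 to 3.83 ± 1.04 CPM (-2.67 ± 0.47, adjusted p = 0.00309, and 0.103 with the muscle covariate at -3.39). Il1b changed by -2.08 ± 0.28, from 92.4 ± 19.3 to 21.8 ± 10.1 CPM, Cxcl1 by -2.23 ± 0.28 and Cxcl5 by -2.14 ± 0.37. The immunoglobulin gene Igha changed by -2.49 ± 0.25 and Ankrd1 by -2.06 ± 0.24. Cytokines as a list had 14 of 23 lowered (17 lowered and 2 raised adjusted over the list alone, median -1.41, adjusted p = 0.165 with an estimated correlation). AP-1 genes had 9 of 16 lowered (13 lowered and 1 raised over the list alone, median -0.53). Their adjusted p was 0.0329 with an estimated correlation, and fry called 8 lists. Fos went from 88.4 ± 16.9 to 39.1 ± 4.2 CPM (-1.18 ± 0.14), near the 34.2 ± 3.39 CPM of control skin. Fosl2 changed by -0.48 ± 0.07.

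Matrix proteases had 11 of 18 lowered with SNX-5422 after CEES (14 adjusted over the list alone, median -0.78) and sebaceous and cholesterol genes 10 of 18 (15 over the list alone, median -0.61), each at an adjusted p of 0.153 with an estimated correlation. Plaur changed by -1.39 ± 0.19, Mmp12 by -1.18 ± 0.13 and the wax synthase gene Awat1 by -1.70 ± 0.28. Neutrophil markers had 6 of 16 lowered (10 over the list alone, median -1.07, adjusted p = 0.271 with an estimated correlation) and monocyte markers 6 of 15 (7 over the list alone, median -0.34, adjusted p = 0.354 with an estimated correlation). Csf3r changed by -1.80 ± 0.30, and Mrc1 by -1.31 ± 0.22 to 322 ± 72.7 CPM, still above the 35.3 ± 1.98 CPM of control. The unfolded protein list had 4 of 20 lowered and 1 raised (6 and 1 over the list alone, median -0.23, adjusted p = 0.271 with an estimated correlation), with Atf3 going from 27.9 ± 1.76 to 13.9 ± 1.80 CPM. Cell death genes had 2 of 17 lowered (7 over the list alone, median -0.27, adjusted p = 0.257 with an estimated correlation), and fibroblast genes 1 raised and 1 lowered of 17 (1 and 1 over the list alone, median -0.32, adjusted p = 0.668 with an estimated correlation).

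Of the keratinocyte lists, basal keratinocyte genes had 8 of 14 raised with SNX-5422 after CEES (8 adjusted over the list alone, median 0.31, adjusted p = 0.153 with an estimated correlation), with Col17a1 at 0.53 ± 0.10 and Lama3 at 0.38. Cornified layer genes had 4 of 20 raised (9 over the list alone, median 0.59, adjusted p = 0.257 with an estimated correlation). Tgm3 went from 32.7 ± 2.90 to 79.1 ± 17.1 CPM (1.28 ± 0.19), beside 69.4 ± 12.8 in control, and Rptn from 22.3 ± 3.86 to 135 ± 61.4 CPM. Wound keratins and stress genes had 4 raised and 2 lowered of 15 (6 and 2 over the list alone, median 0.64, adjusted p = 0.355 with an estimated correlation). Krt6b rose by 1.73 ± 0.26 from 368 ± 43.9 to 1224 ± 552 CPM and Krt16 by 1.34 ± 0.21, while Il1rn changed by -0.62. Interferon-stimulated genes had 4 of 18 raised (6 over the list alone, median 0.55, adjusted p = 0.257 with an estimated correlation), with Ifit3 at 1.43 and Cxcl9 at 2.26.

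Muscle genes were higher too, 15 of 17 (15 adjusted over the list alone, median 1.02, adjusted p = 0.153 with an estimated correlation), with Ckm at 1.21 ± 0.18 and Neb at 1.07 ± 0.15, and so were 6 of 10 mitochondrially encoded genes (6 over the list alone, median 0.68, adjusted p = 0.189 with an estimated correlation). The largest rises were partly in pancreas genes. Ins1 rose by 3.06 ± 0.63, Ins2 by 3.00 ± 0.56 and Gcg by 3.79 ± 0.82 (without SNX-5422+CEES 3 2.73, adjusted p = 0.0578). Of the 38 pancreas genes tested here edgeR called 6 (26 at an unadjusted p under 0.05), DESeq2 22 and limma-voom 0, so these calls depend on the tool. The embryonic muscle genes Myh3 and Actc1 rose by 2.66 ± 0.57 and 2.55 ± 0.57. Without CEES 2 they rose by 4.33 and 4.50, and without CEES 3 Actc1 stood at 2.14 (adjusted p = 0.0557). With the muscle covariate some calls ended with a smaller fold, those of Krt6b (log2 fold change 1.17, adjusted p = 0.186), Krt16 (0.82, 0.202), Col17a1 (0.34, 0.242), Ckm (0.47, 0.178), Neb (0.49, 0.0634), Actc1 (2.16, 0.288), Ifit3 (1.11, 0.114) and Ankrd1 (-1.20, 0.0696). Others ended with a fold near the first or larger, those of Cxcl1 (-2.15, 0.051), Cxcl5 (-2.84, 0.0616), Plaur (-1.29, 0.0525), Mrc1 (-1.47, 0.0583), Lama3 (0.37, 0.0685), Il1rn (-0.74, 0.0733), Myh3 (2.77, 0.221) and Ins1 (3.74, 0.051).

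**Figure D3:**
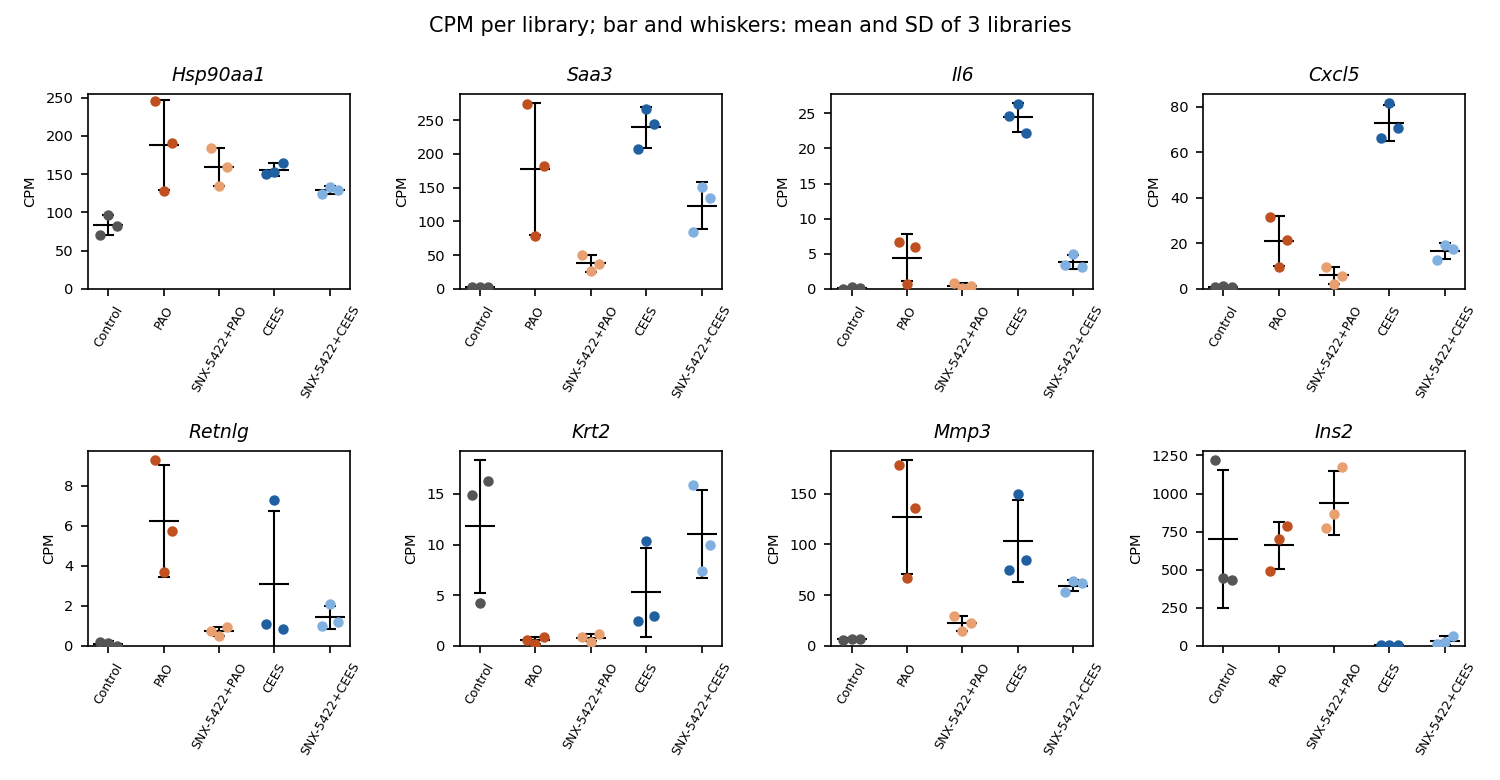
Expression of 8 genes in CPM in the 15 libraries, one point per library, each gene on its own linear axis, with the mean and SD of each group of 3. Il6 averaged 24.4 CPM after CEES and 3.83 CPM where SNX-5422 followed, and Ins2 699.7 CPM in control and 4.23 CPM in CEES libraries.

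SNX-5422 changes often ran against those of the agent. Of the genes called for PAO, SNX-5422 moved 686 the opposite way (513 raised by PAO and lowered by SNX-5422, 173 the reverse) and 50 the same way. The number was 303 without PAO 1, 322 without PAO 3, 311 without SNX-5422+PAO 2, 338 without SNX-5422+PAO 3, 424 with the muscle covariate and 347 with the mitochondrial ribosomal RNA covariate. Independent lists would share 90.6 and 49.7. For CEES 1236 went the opposite way (652 and 584, independent lists 138 and 129) and 36 the same way. That number was 722 without CEES 2, 773 without CEES 3, 776 without SNX-5422+CEES 2, 681 without SNX-5422+CEES 3 and 654 with the muscle covariate. Both comparisons use the libraries of the agent alone, which makes fold changes run opposite without any SNX-5422 effect. Libraries simulated with the agent effect alone had 0.1 and 0.2 genes called for SNX-5422 per run, so their numbers of opposite genes, at most 1, say nothing of this sharing. The covariance of the fold changes across genes was -0.177 in the PAO arm (simulated -0.0635) and -0.304 in the CEES arm (simulated -0.0566). The slope was -0.34 and -0.31. When each library of the agent alone entered only 1 of the comparisons, a check chosen after the data were seen that leaves 1 of them alone in a comparison, the covariance over 6 divisions was -0.143 to -0.0610 in the PAO arm and -0.324 to -0.211 in the CEES arm.

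A score built from the other agent's genes avoids that sharing. Genes called for CEES, raised minus lowered, scored -0.03 ± 0.29 (SD, n = 3) in PAO and -0.44 ± 0.15 in SNX-5422+PAO libraries, a difference of -0.42 (exact two-sided permutation p = 0.2, the smallest possible being 0.1), and -1.04 in control. It moved to -0.58 without PAO 2 and -0.27 without PAO 1. Genes called for PAO scored 1.35 ± 0.27 in CEES and 0.96 ± 0.15 in SNX-5422+CEES libraries, a difference of -0.39 (exact p = 0.1, the smallest possible), and -0.29 in control. It moved to -0.22 without CEES 2.

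**Figure D4:**
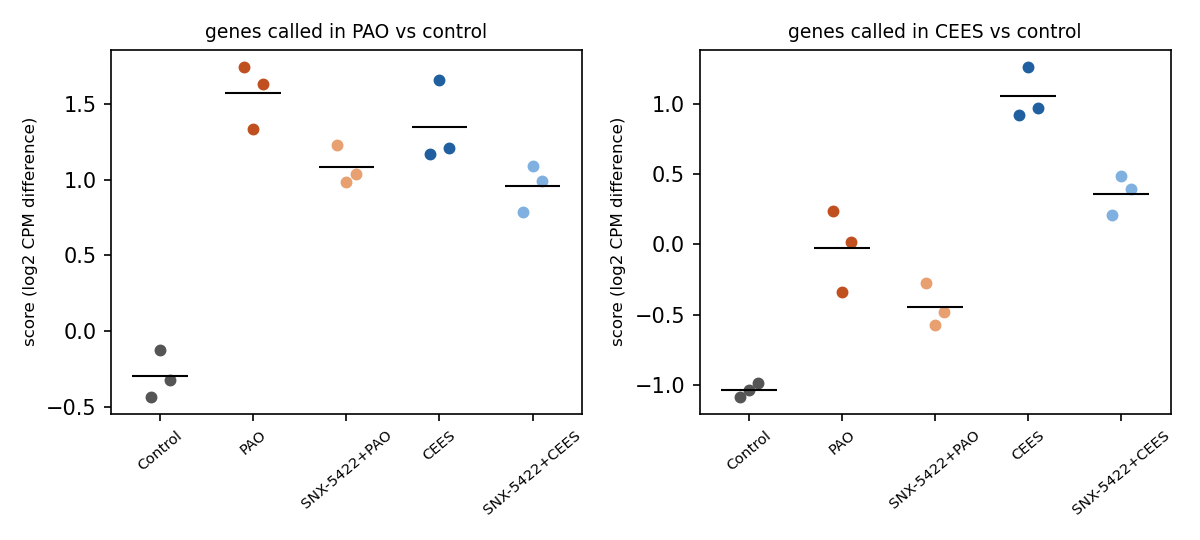
Score of each agent's genes (mean log2 CPM of raised minus that of lowered genes) in each library, one point per library with the group means, drawn for the genes called for PAO and for those called for CEES. PAO and SNX-5422+PAO libraries averaged -0.03 and -0.44 for the CEES genes, and CEES and SNX-5422+CEES libraries 1.35 and 0.96 for the PAO genes.

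Set against control, skin given SNX-5422 after either agent still differed widely. After PAO with SNX-5422 edgeR called 4353 genes, 2401 raised and 1952 lowered. It called 2459 without Control 1, 2427 without Control 3, 2888 without SNX-5422+PAO 1, 2797 without SNX-5422+PAO 3, 998 with the muscle covariate and 449 with the mitochondrial ribosomal RNA covariate, which ended the calls of Krt2 (-4.86, adjusted p = 0.0651), Krtap4-9 (-2.41, 0.361) and Trap1 (0.27, 0.294). Upper-quartile scaling gave 1698 raised and 2414 lowered, and total counts 646 and 6855, with a shift of -0.34. All 20 cornified layer genes stayed lowered (20 adjusted over the list alone, median -2.08, adjusted p = 0.149 with an estimated correlation). Heat shock genes had 14 of 20 raised (15 over the list alone, median 0.48, adjusted p = 0.396 with an estimated correlation), with Hsp90aa1 at 0.94 ± 0.18 and Trap1 at 0.35 ± 0.08 (adjusted p = 0.144 and 0.169 with the muscle covariate). Hsp90ab1 (0.36) and Hsp90b1 (0.43) lost their calls without Control 3 (adjusted p = 0.06 and 0.0505), SNX-5422+PAO 1 (0.0959 and 0.0809) or SNX-5422+PAO 3 (0.0525 and 0.0545). The largest changes were in Igfn1 (8.19), Myh7 (8.05), Tnnc1 (5.59), Krtap4-9 (-4.32), Krt2 (-3.88) and Skint9 (-3.57 ± 0.32).

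After CEES with SNX-5422 edgeR called 5035 genes against control, 2951 raised and 2084 lowered, and 3268 without SNX-5422+CEES 2. Upper-quartile scaling gave 2501 raised and 2861 lowered. Cytokines had 14 of 23 raised (16 adjusted over the list alone, median 2.29, adjusted p = 0.131 with an estimated correlation), and wound keratins and stress genes 9 raised and 2 lowered of 15 (10 and 2 over the list alone, median 2.24, adjusted p = 0.219 with an estimated correlation). Sebaceous and cholesterol genes had 15 of 18 lowered (18 over the list alone, median -0.78, adjusted p = 0.131 with an estimated correlation). Lce3d was at least 303-fold higher than in control, Lce3c rose by 6.92 ± 0.45 and Fgf23 by 5.64, and G6pc2 (-5.05), Zg16 (-5.01) and Pyy (-4.60), genes of the pancreas and gut, were lower. Hsp90b1 rose by 0.51 ± 0.11. Hsp90aa1 rose by 0.63 ± 0.17 (adjusted p = 0.0159), a call that ended without Control 1 (adjusted p = 0.0764), Control 3 (0.0523) or SNX-5422+CEES 2 (0.0521). Hsp90ab1 stood at 0.074 (adjusted p = 0.616) and Trap1 at 0.18 (adjusted p = 0.0906).

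The last comparisons asked what SNX-5422 did after either agent and where its effects differed. On average over both agents 2602 genes were called, 1215 raised and 1387 lowered, or 764 with the muscle covariate and 688 raised and 2992 lowered under total counts (shift -0.12). The SNX-5422 effects, which share no libraries, moved 366 genes the same way in both arms (171 up, 195 down, independent lists 20.5 and 26.4) and 24 in opposite ways, with r = 0.22 across genes. Csf3 (-3.27 ± 0.36), Fgf23 (-2.27 ± 0.36) and Cxcl1 (-2.14 ± 0.21) had the largest mean falls and Igfn1 (5.18) and Tnnc1 (2.74) were among the 3 largest rises with Myh7, which has no fold here because it rests on 2 counts over the PAO libraries. With the muscle covariate Fgf23 (log2 fold change -3.18, adjusted p = 0.0783), Igfn1 (2.36, 0.755), Tnnc1 (2.07, 0.279) and Myh7 (adjusted p = 0.301) were not called. Matrix proteases had 14 of 18 lowered (1 raised and 16 lowered adjusted over the list alone, median -0.88, adjusted p = 0.156 with an estimated correlation), and cytokines 14 of 23 (15 over the list alone, median -1.03, adjusted p = 0.19 with an estimated correlation). Muscle genes had 15 of 17 raised (17 over the list alone, median 0.82, adjusted p = 0.156 with an estimated correlation). Hsp90aa1 stood at -0.26 (adjusted p = 0.208), Hsp90b1 at -0.15 (0.242), Hsp90ab1 at 0.040 (0.769, -0.085 under total counts) and Trap1 at 0.093 (0.312, -0.029 under total counts).

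The SNX-5422 effect itself differed between the agents in 166 genes, 124 with the higher effect after CEES and 42 with the lower. It was 899 without a filter, 694 with DESeq2, 375 with the muscle covariate and 90 with limma-voom. The number moved with most single libraries too. It was 99 without Control 3, 96 without PAO 1, 45 without PAO 3, 101 without SNX-5422+PAO 2, 47 without SNX-5422+PAO 3, 54 without CEES 1, 283 without CEES 2 and 45 without CEES 3. Without SNX-5422+CEES 1, 2 and 3 it was 404, 63 and 41. Krt6b differed by 2.95 ± 0.37 (adjusted p = 0.00165), lowered by SNX-5422 after PAO and raised after CEES. Wound keratins and stress genes as a list had 4 of 15 with the higher effect (11 and 1 lower adjusted over the list alone, median 1.34, adjusted p = 0.134 with an estimated correlation) and sebaceous and cholesterol genes 2 of 18 with the lower (13 over the list alone, median -0.82, adjusted p = 0.134 with an estimated correlation). Tmprss11g differed by 2.87 ± 0.46, and Mybph, a muscle gene, by -3.67 ± 0.23 (adjusted p = 5.58e-07). Lce1a2 (2.75) lost its call without PAO 3 (adjusted p = 0.0555) or SNX-5422+CEES 3 (0.0522). Cxcl3 (-2.94) lost its call without PAO 1 (0.05), PAO 3 (0.0753), SNX-5422+PAO 3 (0.0745) or SNX-5422+CEES 3 (0.0699). The HSP90 genes differed by -0.038 (Hsp90aa1, adjusted p = 0.973, 0.000515 under total counts), 0.22 (Hsp90ab1, 0.519), -0.18 (Hsp90b1, 0.673) and -0.078 (Trap1, 0.827).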

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

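The tests on pancreatic transcripts, on muscle RNA and on shared libraries were chosen after the results were seen; the splits of the samples were planned.

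A test of the difference between the SNX-5422 effects after CEES and after PAO set 166 genes apart. Among the named genes the difference (CEES minus PAO, log2) was 2.95 for Krt6b, 2.87 for Tmprss11g, 2.75 for Lce1a2, -3.67 for Mybph, -3.12 for Tnni1 and -2.94 for Cxcl3. The call of Tnni1 (adjusted p = 0.0422) ended without Control 3 (0.0655), PAO 1 (0.0732), PAO 2 (0.0666), PAO 3 (0.089), SNX-5422+PAO 1 (0.0584), SNX-5422+PAO 3 (0.0867), CEES 1 (0.108), CEES 2 (0.0544), CEES 3 (0.0582) or SNX-5422+CEES 3 (0.102). camera set 14 lists apart at its preset correlation, and none of them with an estimated correlation, where 7 had an unadjusted p under 0.05 and the lowest adjusted p was 0.134, while fry called 7. Their median differences were 0.37 for NRF2 targets, -0.45 for mitotic genes, -0.67 for neutrophil markers, 0.70 for T cell, Langerhans cell and mast cell markers, 1.03 for interferon-stimulated genes, 1.34 for wound keratins and stress genes, 0.96 for the cornified layer, 0.46 for basal keratinocyte genes, 0.68 for endothelial markers, -0.82 for sebaceous and cholesterol genes, 0.36 for skeletal muscle, 0.38 for mitochondrially encoded genes, 0.36 for glucocorticoid receptor targets and -0.16 for AP-1 genes.

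Of 100 splits of the samples within the agents, drawn from 200 possible, 4, the real one included, gave a difference in as many genes. That share lies under 0.05, but it does not exclude chance. A split that mixes SNX-5422 and agent libraries within an arm moves the SNX-5422 effect into the spread, and most such splits called 0 genes. The splits therefore cannot decide whether the effect differed between the agents. The real number of 166 also moved to 41 without SNX-5422+CEES 3. The 3 other splits called 205, 1077 and 2602 genes. The split with 2602 exchanged the labels of all 6 libraries in the CEES arm and none in the PAO arm, which turns the mean SNX-5422 effect into the difference, so that number reflects a structure of the samples. The splits with 205 and 1077 exchanged all 6 and 2 PAO libraries besides, but 4 further splits with all 6 exchanged called 0, 0, 0 and 129 genes, so what set them apart stays open. For the mean effect, 1 of 100 splits, the real one, reached 2602, and the highest other reached 166. The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05, and in each of them only 1 split, the real one, reached the real number. The highest other split of PAO and control called 0 genes with edgeR, against 4607 (up to 3142 at an unadjusted p under 0.05). For CEES and control it called 0 against 7640 (1767 unadjusted), for SNX-5422+PAO and control 0 against 4353 (3275 unadjusted), and for CEES and PAO 0 against 4255 (1495 unadjusted). For SNX-5422+PAO and PAO the highest other was 97 against 1343, for SNX-5422+CEES and CEES 3 against 1576, and for SNX-5422+CEES and control 64 against 5035. The other tools were not run on the splits.

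Outside the gene counts, reads with more than a single alignment made up 8.18% ± 1.09 (SD, n = 3) of the PAO libraries and 8.88% ± 0.862 of the SNX-5422+PAO libraries. Every one of these libraries lay above the control libraries, which ranged from 4.78 to 6.65%.

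Pancreatic transcripts were present in all libraries without CEES and much lower in the others. SNX-5422+CEES 3 still held 153 CPM of islet and 69.5 CPM of acinar transcripts, beside 892 and 310 CPM in Control 3, the lowest of the libraries without CEES. Of the 38 genes tested, 37 were lower after CEES than in control (median log2 -6.58; 37 by DESeq2 and by limma-voom). Islet and acinar sums, centred within groups, rose and fell together over the 15 libraries (Pearson r = 0.944, permutation p = 0.00049, Spearman rho = 0.961, p = 0.00077, r = 0.971 without the 2 farthest). Any common source of both, pancreas tissue or other, would give this. Transcripts made steadily by skin are argued against, since the within-group SD of these genes in the 9 libraries without CEES lay at a median percentile of 99.0 among genes of like expression. Separate handling of the CEES groups cannot be told apart from treatment, because 0 libraries carry a code within the range of the other arm. The most abundant identifier without a symbol divided the libraries in the same way. It took 2.64 to 6.68% of gene counts in libraries without CEES and 0.322 to 1.71% in those with it, and the cause was not tested. No biological explanation was tested beyond these.

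SNX-5422 changes ran opposite to those of the agent in 686 genes after PAO and 1236 after CEES. The libraries of the agent alone enter both comparisons, which can raise these counts. These libraries were divided in 6 ways so that the comparisons shared none, with 1 library alone in a comparison. The covariance of the fold changes stayed negative, nearest 0 at -0.0610 after PAO (SD over divisions 0.0334) and -0.211 after CEES (SD 0.0401). The divisions reuse these libraries, so this SD is no sampling error and chance among the libraries stays open. More muscle RNA diluting the skin RNA would lower other cell types alike, and the falls would go with muscle content. With the muscle covariate the 513 genes raised by PAO and lowered by SNX-5422 moved by a median of -0.0122 (SD of single genes 0.260), where 0.782 would take their median to 0, and the 652 such genes after CEES by -0.0280 (SD 0.428), where 0.743 would. The slope of that covariate comes from the spread of muscle content within groups. In PAO libraries this spread was narrow (mean centred log2 CPM of the muscle list 0.0974 to 0.149). The genes were also chosen for their calls in the same comparison. These values therefore cannot decide whether dilution caused the falls. After CEES the basal keratinocyte median (0.31) lay above the cytokine median (-1.41) by 1.73, against an SD of single members of 0.737. This argues against an even dilution of all skin RNA as the whole cause of the falls there. After PAO that distance was 0.787 (-0.05 and -0.84) against an SD of 0.976, which leaves dilution open. With the covariate the 173 genes lowered by PAO and raised by SNX-5422 moved by -0.102 (SD 0.347), where -0.852 was needed. The 584 such genes after CEES moved by -0.304 (SD 0.494), where -0.852 was needed, so part of that rise goes with muscle content. The covariate's limits hold here too, so whether muscle RNA caused these rises stays undecided. With the covariate 208 of the 513 and 65 of the 173 stayed called, and 140 of the 652 and 69 of the 584. For the falls the median fold stayed near its value (-0.782 to -0.768 after PAO, -0.743 to -0.740 after CEES) while the median SE grew (0.164 to 0.216 and 0.159 to 0.270). For the rises the fold shrank too, from 0.852 to 0.721 (median SE 0.164 and 0.187) and from 0.852 to 0.451 (0.173 and 0.211). An effect of SNX-5422 on the injury itself remains an open hypothesis in both arms.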

How the results depend on the processing

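The alternatives without pancreatic genes, with a pancreas covariate, without ribosomal RNA and unnamed identifiers and with mitochondrial ribosomal RNA as a covariate were chosen after the data were seen; all others were planned. Unless stated otherwise, the cause of a change was not tested.

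Of the 421 results for named genes, 419 kept direction and side of the threshold with DESeq2 size factors, 418 with upper-quartile scaling, 388 with total counts, 415 without a filter, 421 with the 1 CPM filter, 419 with DESeq2, 387 with limma-voom, 407 with robust edgeR and 399 in fits of the groups compared alone. With the muscle covariate 292 did, with the pancreas covariate 195, with the mitochondrial ribosomal RNA covariate 362, and without ribosomal RNA 419. Without other-tissue lists all 386 that could be tested did, and without pancreatic genes all 410. Leaving out 1 library kept 380 to 415. Of the 107 list calls in the 4 main comparisons, CEES against PAO and the difference of SNX-5422 effects, 2 held with an estimated correlation and 75 with fry, 106 with size factors, 105 without a filter and 86 with the muscle covariate. With an estimated correlation camera called 1 list for PAO against control and 1 for SNX-5422+CEES against CEES. In the other 7 comparisons it called 0, where 3 to 8 had an unadjusted p under 0.05 and fry called 7 to 19. fry called 7 lists for SNX-5422+PAO against PAO (18 by camera), 8 for SNX-5422+CEES against CEES (15), 7 for the difference of SNX-5422 effects (14) and 10 for their mean (16). All 95 that could be tested without other-tissue lists held, and all 107 without pancreatic genes. Both fits drop only the listed genes and leave other RNA of those tissues in place, so they do not test its influence.

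A fold change above 2 as a further condition can only lower counts. It left 1602 genes for PAO and 3086 for CEES against control, 440 for SNX-5422+PAO against PAO, 508 for SNX-5422+CEES against CEES, 1371 and 1891 for the SNX-5422 groups against control, 1638 for CEES against PAO and 438 for the mean SNX-5422 effect. The score of CEES genes in PAO libraries then moved to -0.67.

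With muscle content as a covariate the counts were 627 for SNX-5422+PAO against PAO, 727 for SNX-5422+CEES against CEES, 998 for SNX-5422+PAO against control, 1688 for CEES against PAO, 375 for the difference of SNX-5422 effects and 764 for their mean. Genes moved opposite to the agent numbered 424 after PAO and 654 after CEES. The pancreas covariate nearly separates the CEES groups from the rest by construction. With it edgeR called 0 genes for CEES against control (2160 at an unadjusted p under 0.05, 190 by DESeq2, 1 by limma-voom) and 0 for CEES against PAO (1802 unadjusted, 44 and 1). It called 334 for SNX-5422+CEES against CEES, 14 for SNX-5422+CEES against control, 40 for the difference and 1184 for the mean. With mitochondrial ribosomal RNA as a covariate, which was higher in both PAO groups than in control, edgeR called 2035 genes for PAO against control, 449 for SNX-5422+PAO against control and 827 for CEES against PAO. The overlap of the agents was then 1540, and 347 genes went opposite after PAO. Total counts gave 7501 genes for SNX-5422+PAO against control and 7863 for CEES against PAO. The difference of SNX-5422 effects numbered 899 without a filter, 694 with DESeq2 and 90 with limma-voom.

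Leaving out 1 library gave 2953 to 4920 genes for PAO and 6169 to 7905 for CEES against control, 566 to 1605 for SNX-5422+PAO against PAO, 806 to 1825 for SNX-5422+CEES against CEES, 2427 to 5013 and 3268 to 5400 for the SNX-5422 groups against control, 2825 to 4467 for CEES against PAO, 41 to 404 for the difference and 1934 to 2844 for the mean. The overlap of the agents ranged from 1985 to 3259, opposite genes from 303 to 877 after PAO and from 681 to 1392 after CEES, and the scores from -0.58 to -0.27 and from -0.49 to -0.22. A group left with 2 libraries shares the spread estimated from all groups.

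No replicate number pairs the samples. Same-number correlations of deviations from group means ran from -0.10 to 0.10, 1 of 18 of them over 0.1, and those of other pairs from -0.09 to 0.12. With the replicate block, in the 12 libraries whose titles number 1 to 3, edgeR called 4058 genes for PAO against control (4508 in these libraries without the block), 7086 (7523) for CEES against control, 1072 (1277) for SNX-5422+PAO against PAO, 3666 (4201) for SNX-5422+PAO against control and 3697 (4082) for CEES against PAO. Of 314 named gene results 9 were no longer past the threshold, Trap1 after PAO among them (adjusted p = 0.0802).

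These values changed sign, and most were not called to begin with. With total counts Hsp90ab1 turned to 0.0438 for CEES against control and -0.0848 for the mean SNX-5422 effect, Trap1 to -0.0585 for SNX-5422+CEES against CEES, 0.23 for CEES against PAO and -0.0292 for the mean, and Hsp90aa1 to 0.0324 for CEES against PAO and 0.000515 for the difference of SNX-5422 effects. With the muscle covariate Hsp90ab1 turned to 0.0462 for CEES against control and -0.0604 for the mean, Trap1 to -0.0481 for SNX-5422+CEES against CEES and 0.0240 for CEES against PAO, Hsp90aa1 to 0.12 for CEES against PAO, Ccng1 to -0.13 for SNX-5422+CEES against CEES, and Aldoa to 0.16 for CEES against control, -0.15 for SNX-5422+CEES against CEES and 0.0270 for CEES against PAO. The muscle list, the covariate itself, turned to -0.0514 for SNX-5422+PAO against PAO. With the mitochondrial ribosomal RNA covariate Hsp90b1 turned to 0.0330 for SNX-5422+PAO against PAO and to -0.0141 for CEES against PAO. With the pancreas covariate Cd3e turned to 1.01, Tgm3 to 0.0332, Awat1 to -0.0831 and Sult1a1 to 0.18 for CEES against control, Hsp90ab1 to -0.0840 for SNX-5422+CEES against control, Hsp90b1 to -0.0153 and Phlda3 to 0.17 for CEES against PAO, and Hsp90aa1 to 0.10 for the difference.

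Leaving out 1 library also turned signs of genes that were not called. For SNX-5422+PAO against PAO Hsp90ab1 ranged from -0.16 without SNX-5422+PAO 1 to 0.00796 without PAO 1, and Hsp90b1 from -0.19 without PAO 2 to 0.0854 without PAO 1 (0.0126 without SNX-5422+PAO 2). For the difference Hsp90aa1 ranged from -0.30 without PAO 1 to 0.15 without PAO 2 (0.0595 without SNX-5422+PAO 1 and 0.00279 without CEES 3). For the mean Hsp90ab1 ranged from -0.0183 without SNX-5422+PAO 1 to 0.0647 without PAO 1 (-0.0181 without PAO 2).

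Depth limits genes of few counts. Lce3d and Il19 in control, Myh7 and Lce3d after PAO and Zg16, Ppy and Pcsk1n after CEES rest on 3 counts or fewer per group, and their folds are bounds or intervals.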

Other observations

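The genes below were singled out after their values were seen, and no explanation is offered for them.

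Gm4737 and Gm7292 were present in SNX-5422+PAO libraries at 8.77 to 9.20 and 9.74 to 10.7 CPM and in CEES 1 and 3 at 9.57 and 8.12 CPM (Gm4737), but read 0.122 and 0.163 CPM in CEES 2 and at most 0.577 and 0.535 CPM in any library of the other groups. Gm6768 averaged 2.76 CPM in control and 3.82 CPM in SNX-5422+CEES libraries and 0.109 to 0.216 CPM in the other groups. Rpl26 averaged 72.4, 76.1 and 84.2 CPM in the control, PAO and SNX-5422+PAO groups and 10.7 and 11.4 CPM in CEES and SNX-5422+CEES. These are copies of, or have copies among, near-identical genes, and the counting leaves their levels uncertain. That uncertainty concerns the levels, and no cause of the differences between libraries was tested. Ighg2c averaged 3.33, 4.32 and 5.89 CPM in the groups without CEES and 0.117 and 0.0805 CPM in those with it.

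Some muscle genes were higher after either agent than in control, although the muscle list of 17 had 1 raised and 1 lowered after PAO and 15 lowered after CEES. Ankrd2 averaged 9.26 CPM in control and 210.2 CPM after PAO, Mustn1 14.7 and 227 CPM, Xirp1 79.0 and 504 CPM, Flnc 491 and 2317 CPM and Myog 1.94 and 9.92 CPM. After CEES they averaged 75.6 CPM (Ankrd2), 68.2 CPM (Mustn1), 178 CPM (Xirp1), 1500 CPM (Flnc) and 5.86 CPM (Myog). With SNX-5422 after PAO, Ankrd2 averaged 131 CPM, Mustn1 124 CPM, Xirp1 794 CPM, Flnc 2954 CPM and Myog 11.3 CPM.

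Islet transcripts in libraries 1, 2 and 3 summed to 2446, 923 and 892 CPM in control, 1006, 1465 and 1602 in PAO, 1603, 1789 and 2417 in SNX-5422+PAO, 16.6, 17.3 and 21.6 in CEES and 29.9, 65.6 and 153 in SNX-5422+CEES.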
